A study of Mus musculus with 7 samples.

How the data were processed

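The series measured messenger RNA in 7 single mouse embryos of the C57BL/6 background, collected at the morula stage, 3 days post coitum, from crosses between parents that each carry 1 mutant copy of L13a. L13a is the gene with the symbol Rpl13a, which encodes a protein of the large ribosomal subunit. Per the labels' protocols, embryos were flushed from the oviduct or uterus, washed, lysed and heated, and RNA was purified with a PicoPure kit. RNA amounts were evened out, cDNA was made from polyadenylated RNA with SMART-Seq v4, and libraries were made with Nextera XT. That method carries no molecular identifiers, so amplified copies of 1 molecule cannot be told from separate molecules. The labels put all 7 embryos in 1 group, numbered 1 to 7, and give no genotype, sex, litter or batch. No embryo was given a genotype from its Rpl13a level or from any other value, and no groups were compared. Because the labels do not say that the embryos came from separate litters, p-values measure the spread between these samples, which may be technical.

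Both tables were made by the authors with HISAT2 2.0.5, featureCounts 1.5.0-p2 of the Subread package, limma and the mouse genome build GRCm38, per the submitters' processing notes. The order of the steps, their settings, the gene annotation and the use of strand are not given in the sources used here. The deposited count table holds whole-number counts of reads for 26586 gene symbols with no normalization. The deposited log2 table holds normalized values that were recomputed here from the counts as log2 CPM (counts relative to the library total, on the usual fixed scale) with a small offset, followed by quantile normalization. The recomputed and deposited log2 values differed by at most 4.97e-14. Quantile normalization gives every library the same set of values, so a count of 0 stands at -2.65 and the highest gene at 15.67 in all 7 columns, whatever the depth. All columns of both tables were used. Of the 26586 symbols, 22468 matched a gene name in GENCODE release M21 of GRCm38, which served for positions.

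Counts were scaled with TMM factors in edgeR 4.0.16 under R 4.3.3, and log2 CPM were computed with a prior count of 2. CPM printed for single genes are counts over the library total, without the TMM factor. Genes with a mean CPM of 1 or more were kept, which left 11810. The test of spread asked for each gene whether its quasi-likelihood dispersion over the 7 embryos exceeded that of genes of like abundance, with a one-sided F test and Benjamini-Hochberg adjustment at 0.05. The prior degrees of freedom were those of genes that robust estimation does not down-weight. This was set after tests on simulated data, in which the version with each gene's own prior recovered 0% of 200 genes with 20-fold raised dispersion at any noise level; that version is kept as an alternative. At a dispersion of 0.1, the version used recovered 98% of the 200 genes with 2 false calls among 11806 genes. At the dispersion of the real libraries it recovered 0% of 200 among 11250 genes, so a count of 0 genes says little about the spread of any 1 gene. The slope test, an edgeR quasi-likelihood test of each gene against the log2 CPM of Rpl13a, recovered 100% of 200 genes of slope 1 at a dispersion of 0.1, with 7 false calls among 11799 genes, and 0% of 200 among 11307 genes at the real dispersion.

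Each of 30 gene lists with 776 entries was fixed before the data were examined, as were the tests, the rule for named genes and all alternatives except those named as added later. The table held 760 of the entries, 16 of them under an older symbol. A list's score in an embryo was the mean log2 CPM of its members with a mean CPM of 1 or more, given for lists with at least 3 such members. The SD of the score over the 7 embryos was ranked among 10000 random lists of the same size drawn from 20 bins of mean expression. A list at or above percentile 95 was called high. Of 100 random lists scored the same way, 6% reached that percentile. Pearson's r and Spearman's rho were tested with two-sided exact permutation tests over all pairings of the 7 embryos, and p-values were adjusted over each family by the Benjamini-Hochberg method. Among 400 simulated unrelated pairs, 4.5% had an exact permutation p under 0.05. No r was given where the largest gap between neighbouring values was more than 0.5 of their range, a rule applied to the Rpl13a values and to the first list of a pair. The smallest exact p that 7 embryos allow is 0.000198. For the slope test, the Rpl13a values were also put in 100 random orders. For DESeq2, 20 random orders were drawn because of the run time.

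The named genes were Rpl13a, the 10 genes of highest median CPM, up to 25 genes past the test of spread, the member of highest mean CPM of each list with its members past the test, up to 3 ribosomal protein genes with a larger SD than Rpl13a, Xist and the Y-linked genes, and up to 10 genes of each sign past the slope test. As 0 genes passed either test, those parts of the rule named none. The following were chosen after their values were seen: Krt8, Krt18, Cdx2, Gata3, Fabp3, Nanog, Pou5f1, Dppa5a, Gata6, Omt2a, Oosp1, Bmp15, Obox5, Btg4, Zfp352, Tcstv3, Tmem92, Hspa8, Hspa5, Psma7, Cdkn1a, Gapdh, Ifitm3, the tract and immune markers other than Lcn2 and Csf1r, and genes called under 1 alternative only. Ribosomal protein genes, keratins, Gapdh and Hsp90ab1 have pseudogenes or close relatives with which the authors' counting could share reads, and their values are uncertain for that reason. The same holds for the Obox, Omt2, Oosp and Tcstv families.

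Total counts ran from 139619 to 33123742 per library. A limit of 3 counts, the most that a count of 0 allows at 95% confidence, equals 21.5 CPM in replicate 6 and 0.0906 CPM in replicate 4. Intervals are exact Poisson intervals for counts and Clopper-Pearson intervals for shares. All intervals and limits cover counting error only. Rn45s, Rnr1, Rnr2 and Lars2 stayed in the totals, and leaving them out was an alternative. The alternatives fixed in advance were DESeq2 size factors (DESeq2 1.42.0), scaling by the library total, the authors' log2 table tested with limma 3.58.1, a prior count of 0.5, no filter or a mean CPM of 10, prior estimation without the robust step, a chi-square test and DESeq2 dispersion outliers, thinning of all libraries to the lowest total, medians over list members (ranked among 1000 random lists), a DESeq2 Wald test of the slope, and leaving out each embryo or the 2 farthest from the median of Rpl13a, of the first list of a pair or of the technical measure. An adjusted p equal to 0.05 did not pass. Alternatives chosen after seeing the data were the bias-adjusted quasi-likelihood fit of edgeR, each gene's own prior, leaving out the 2 libraries of fewest counts (replicates 3 and 6), leaving out Rn45s, Rnr1, Rnr2 and Lars2, residuals on log10 total count, the gap rule applied to both measures, and the comparison of r with that of random lists (for pairs, in place of the second list). Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.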

Results

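Single mouse embryos at the morula stage, when cells compact and the outer ones begin to form trophectoderm, were profiled by RNA sequencing. All came from crosses of mice heterozygous for a mutation of L13a (Rpl13a), and the series describes the transcriptome of embryos from that cross. The 7 embryos form 1 group, so the report describes Rpl13a, the differences between embryos, and gene groups fixed in advance. Libraries differed 237-fold in total count. Totals were 1143861, 16452890, 725729, 33123742, 2764409, 139619 and 17122136 for replicates 1 to 7, and 5121, 9383, 3486, 12064, 3388, 1749 and 8953 genes had a count. With all libraries thinned to the lowest total, 3914, 6889, 2824, 8570, 2347, 1749 and 6623 genes had a count. Replicate 5 thus had fewer genes than replicates 1 and 3 from a larger total. Only 436 genes had a count in every library, and 11622 had none in any.

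**Figure D1:**
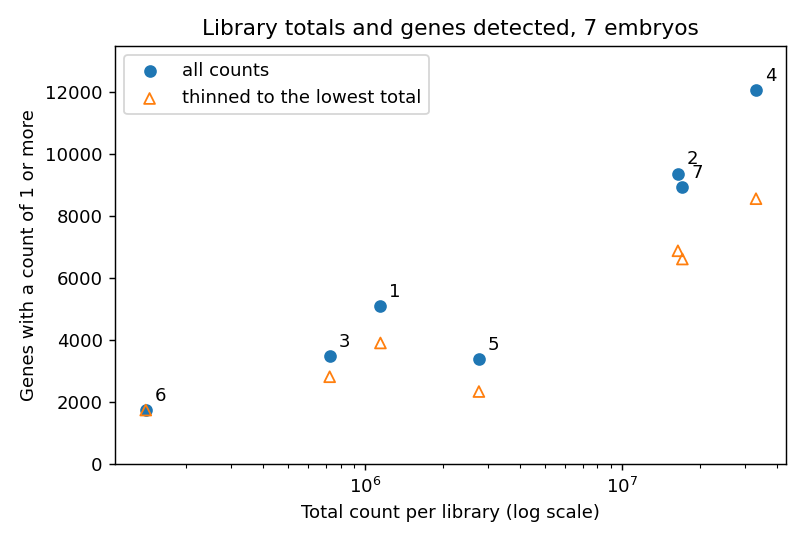
Number of genes with a count of 1 or more (vertical axis) against the total count of each library (horizontal axis, log scale) for the 7 embryos, labelled by replicate number; filled circles use all counts and open triangles the counts thinned to the lowest total. Replicate 6 had 1749 genes from 139619 counts and replicate 4 had 12064 genes from 33123742 counts.

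The most abundant transcripts included ribosomal RNA and several genes known from oocytes. Rn45s, the precursor of cytoplasmic ribosomal RNA, had the highest median, 41631 CPM. Next were reads counted under the symbol Lars2, the gene of a mitochondrial leucyl-tRNA synthetase, at 36580 CPM. Whether the reads counted under Lars2 come from its messenger RNA was not determined. Rn45s, Rnr1 and Rnr2 together took 11.3, 13.2, 3.38, 3.65, 20.4, 8.67 and 4.18% of the counts of replicates 1 to 7, and Lars2 took 3.59, 4.79, 1.19, 1.92, 3.66, 5.19 and 5.87%. Next came Siah2, a ubiquitin ligase, with a median of 5103 CPM, the Axin-binding zinc finger gene Zbed3 with 3374 CPM, and Dppa3 (Stella), which protects maternal methylation after fertilisation, with 2904 CPM. Spin1, a chromatin reader of oocytes, had a median of 2694 CPM, Omt2b, an oocyte transcript, 2607 CPM, and Cdc42se2, an effector of Cdc42, 2418 CPM. Several of these were abundant in most embryos and scarce in 1 or 2. Zbed3 stood at 10247, 3374, 7277, 6.10, 89.0, 2342 and 21207 CPM and Spin1 at 4720, 2034, 2694, 27.1, 1.09, 7671 and 3883 CPM in replicates 1 to 7.

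Embryos differed widely in most genes, and no gene stood out above that spread. The median SD of log2 CPM over the 11810 genes was 3.63, and the common dispersion was 9.02, a coefficient of variation of 3.00 between embryos. Suz12, a Polycomb subunit, with 9.41 ± 0.96 log2 CPM, Cox8a, a cytochrome c oxidase subunit, with 10.28 ± 0.96, and Pttg1 (securin), with 9.28 ± 1.24 (SD, n = 7), were among the named genes of small spread. The proteasome ubiquitin receptor Psmd4, with 4.43 ± 6.17 log2 CPM, and the trophectoderm adaptor Dab2, with 5.24 ± 5.22, were among those of large spread. With the edgeR dispersion test 0 of 11810 genes passed (lowest adjusted p 0.869), 68 had an unadjusted p under 0.05, and DESeq2 gave 0 dispersion outliers. The authors' log2 table tested with limma gave 2 genes, Siah2 (adjusted p 0.0388) and Zbed3 (adjusted p 0.000259). At this noise the test recovered 0% of 200 simulated genes with 20-fold raised dispersion among 11250 genes. Pairwise Spearman correlations between libraries ran from 0.0803 to 0.432 across genes, which are not independent replicates. The lowest chi-square per degree of freedom between any pair of libraries was 122, so no library appeared to be deposited more than once.

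Rpl13a, which encodes a protein of the large ribosomal subunit that also acts in the GAIT complex of translational control, was counted in all 7 embryos at very different levels. Its counts were 99, 1954, 4, 17558, 9, 1 and 403 in replicates 1 to 7. In CPM these were 86.5 (95% Poisson interval 70.3 to 105), 119 (114 to 124), 5.51 (1.5 to 14.1), 530 (522 to 538), 3.26 (1.49 to 6.18), 7.16 (0.181 to 39.9) and 23.5 (21.3 to 26.0). The highest was 163-fold above the lowest, and log2 CPM averaged 4.89 ± 2.92 (SD, n = 7). The CPM intervals of replicates 3, 5 and 6 overlapped, which is not a test of a difference among them. As shares of all ribosomal protein counts, the 95% intervals of replicates 3 (0.0199 to 0.187%) and 5 (0.00210 to 0.00873%) did not overlap. The gene lies on chromosome 7 of GRCm38, from 45125558 to 45128761 on the minus strand (ENSMUSG00000074129.14, 19 annotated transcripts over 3204 bp). Its locus holds Snord32a, Snord33, Snord34, Snord35a and Mir5121 and overlaps Gm45713 on the same strand. A processed pseudogene, Rpl13a-ps1, lies on chromosome 19 from 50030124 to 50030735. The count table has no entry for Gm45713 or Rpl13a-ps1, and the small RNA genes of the locus had at most 59 counts (Snord34 in replicate 4). Whether Rpl13a shares reads with any of these genes was not determined, and such reads would make its level uncertain. The part of the gene that the mutation removes is not given in the sources used here.

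Rpl13a did not vary more than the other ribosomal protein genes. Of the 78 others, 62 had a larger SD of log2 CPM and 16 a smaller one, with a median SD of 4.40 over the measured ribosomal protein genes. Rps18, a protein of the small subunit decoding head, was at 0, 330, 0, 1411, 3331, 0 and 0.467 CPM in replicates 1 to 7 (SD of log2 CPM 6.61). Rps14 had an SD of 6.11 and Rpl10 of 5.67, while Rpsa had the smallest, 1.27. The adjusted p of Rpl13a in the edgeR dispersion test was 0.881. Rpl13a held 1.19% (95% Clopper-Pearson interval 0.968 to 1.45), 0.609% (0.583 to 0.637), 0.0730% (0.0199 to 0.187), 0.762% (0.750 to 0.773), 0.00460% (0.00210 to 0.00873), 0.0463% (0.00117 to 0.258) and 0.374% (0.339 to 0.413) of all ribosomal protein counts in replicates 1 to 7. The median CPM of the other ribosomal protein genes was 32.8, 151, 0, 716, 570, 0 and 42.4. In replicate 5, 1 of the 78 others had a lower count than Rpl13a; in replicates 3 and 6, 45 and 46 did. Without replicates 3 and 6, the number with a larger SD was 39 of 78, an alternative added after seeing the data.

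**Figure D2:**
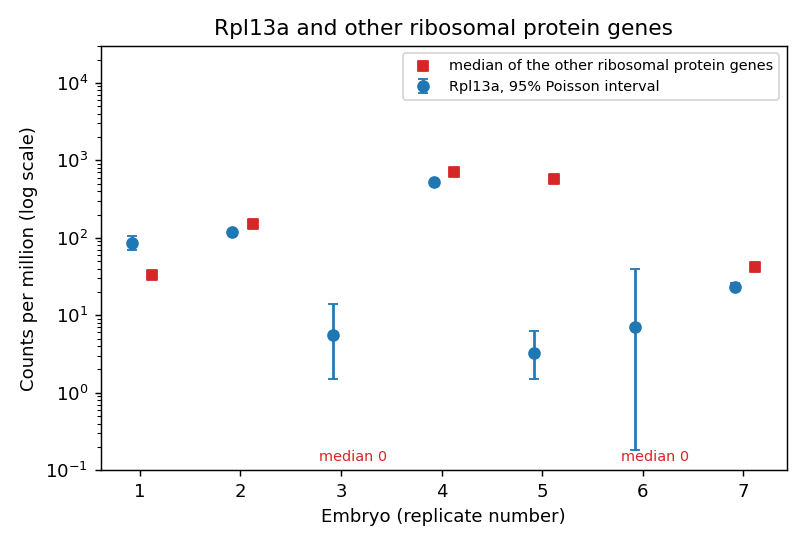
CPM (vertical axis, log scale) of Rpl13a (circles, bars are 95% Poisson intervals) and the median of the 78 other ribosomal protein genes (squares) in each embryo by replicate number (horizontal axis). Rpl13a was at 3.26 CPM in replicate 5 beside a median of 570 CPM, and the median was 0 in replicates 3 and 6.

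Transcripts of the translation machinery differed between embryos as a group. Large subunit ribosomal protein genes scored 3.70, 7.45, 1.39, 9.78, 8.93, 1.03 and 5.22 log2 CPM in replicates 1 to 7 and small subunit genes 4.96, 7.74, 1.96, 9.98, 9.24, 1.62 and 5.44. Together with Rpl13a they made up 0.727, 1.95, 0.756, 6.96, 7.08, 1.55 and 0.629% of the counts. The SD was 3.51 for the large and 3.32 for the small subunit list, above all of the 10000 random lists in each case (percentile 100). Rplp1, of the ribosomal stalk, reached 6794 CPM in replicate 5 and 984 CPM in replicate 4, against 8.27 CPM in replicate 3. Rpsa ranged from 311 CPM in replicate 7 to 3133 CPM in replicate 5. Ribosome biogenesis genes (SD 3.04, percentile 100) and translation factors (SD 2.75, percentile 100) also spread more than random lists. The nucleolar gene Ncl reached 2949 CPM in replicate 3 and was not counted in replicate 6, and the translation factor Eif5a ranged from 23.4 CPM in replicate 3 to 5791 CPM in replicate 4. No member of these lists passed the edgeR dispersion test, over all genes or adjusted over the list alone. That count of 0 in both forms held for each of the 26 lists scored, and the SD of 13 lists was at or above percentile 95.

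Maternal oocyte transcripts and transcripts of the embryo's own lineages were unevenly spread over the embryos. The oocyte list scored 5.97, 7.03, 4.21, 0.92, -0.28, 1.74 and 7.75 in replicates 1 to 7 (SD 3.16, percentile 100). Its 40 measured members summed to 23561, 19726, 27764, 6789, 1251, 16667 and 34082 CPM. Omt2b was at 1781, 4971, 3103, 1.57, 577, 2607 and 6719 CPM, and Bmp15, a growth factor of the oocyte, at 1893, 488, 2939, 0.0600, 0, 279 and 2113 CPM. Btg4, which drives the clearance of maternal RNA, was not counted in replicates 4 and 5 and reached 2545 CPM in replicate 7. The trophectoderm list scored -0.25, 2.48, -1.87, 6.84, -1.03, -1.29 and 0.66 (SD 3.04, percentile 100), with 29 of 30 members counted in replicate 4 and 21 in replicate 2. The keratin gene Krt8 had 42849 counts (1294 CPM) in replicate 4, 1468 (89.2 CPM) in replicate 2 and 0 in the others, where 3 counts equal from 0.175 to 21.5 CPM. Cdx2, the trophectoderm transcription factor, had 3490 counts in replicate 4 and 0 in the other 6 embryos. Dab2, the most abundant member by mean, was at 3065 CPM in replicate 6 and 437 CPM in replicate 4.

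The pluripotency list scored 0.36, 4.39, 0.12, 6.74, 1.55, -0.41 and 2.68 (SD 2.60, percentile 99.3), with all 24 members counted in replicate 4. Nanog had 2596 counts in replicate 4 and 0 elsewhere, and Pou5f1 (Oct4) had 841, 16991 and 5050 counts in replicates 2, 4 and 7 and 0 in the others. Tcl1, a coactivator of AKT that is also abundant in oocytes, went the other way, with 6.88 CPM in replicate 4 and 5742 CPM in replicate 1. The primitive endoderm list (SD 1.93, percentile 55.1) did not spread more than random lists. Its member Fgfr2 peaked at 573 CPM in replicate 3, while Gata6, a transcription factor of that lineage, had 12617 counts in replicate 4 and at most 590 elsewhere. Genes of the 2-cell stage (SD 2.04, percentile 33.2) scored highest in replicate 7, at 5.03. Their most abundant member, Obox6, was at 2462 CPM in replicate 3.

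Cell structure and metabolism lists with a high spread were cell junctions and polarity (SD 2.87, percentile 99.0), nuclear-encoded oxidative phosphorylation (SD 3.16, percentile 100), the proteasome (SD 3.98, percentile 100) and cholesterol and lipid synthesis (SD 2.63, percentile 95.8). The proteasome score was 9.87 in replicate 4 and -1.28 in replicate 3. Epcam, an epithelial adhesion molecule, reached 1499 CPM in replicate 4 and was not counted in replicates 5 and 6. Srebf1, a regulator of lipid synthesis, peaked at 853 CPM in replicate 3. Heat shock proteins also spread more than random lists (SD 2.77, percentile 99.5), with Hsp90ab1 at 8371 CPM in replicate 4 and 8.27 CPM in replicate 3. Lists that did not reach percentile 95 were p53 targets (SD 2.33, percentile 90.4), the integrated stress and unfolded protein response (2.40, 91.1), interferon response and inflammation (2.06, 85.5), the GAIT complex and its targets (2.27, 28.8), the Hippo pathway (2.30, 77.5), mitosis and cell cycle (2.32, 76.5), apoptosis regulators (2.45, 83.9), glycolysis (2.84, 94.4) and DNA methylation and chromatin (2.29, 85.4). Named members of these lists were Sesn2, a stress-induced p53 target (563 CPM at most, in replicate 2), Ddit3 (CHOP; 2800.5 CPM in replicate 6), Stat2 of interferon signalling (2033 CPM in replicate 5), Dapk3, a kinase upstream of L13a (332 CPM in replicate 5), the Hippo effector Yap1 (1253 CPM in replicate 6, 0 in replicate 5), cytochrome c (Cycs; 256 CPM in replicate 5) and pyruvate kinase (Pkm2; 681 CPM in replicate 2).

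Of the 13 lists at or above percentile 95, large and small subunit ribosomal proteins, trophectoderm, oocyte transcripts, oxidative phosphorylation and the proteasome stayed there in every alternative run. With medians over members, ribosome biogenesis (percentile 92.5), translation factors (88.5), heat shock proteins (90.6), pluripotency (90.5), cell junctions (55.5), cholesterol synthesis (22.2) and oviduct and uterine epithelium (83.5) fell below 95. Without replicate 4, translation factors (64.7), heat shock proteins (46.6), pluripotency (72.5), cell junctions (77.0) and cholesterol synthesis (21.6) did. Oviduct and uterine epithelium also fell below without replicate 2 (68.7) or 5 (84.5), with DESeq2 size factors (94.96) and with members of mean CPM 10 or more (93.5). Cholesterol synthesis also did without replicate 5 (90.8), with the library total (93.98), a prior count of 0.5 (94.05) and members of mean CPM 10 or more (93.8). The stress response reached 95 in the authors' table (95.6), after thinning (97.5), with members of mean CPM 10 or more (98.6) and without replicate 5 (96.25), 6 (95.9) or 7 (98.15). Glycolysis did with medians (96.0), after thinning (95.8) and without replicate 4 (97.35), interferon response without replicate 4 (99.2), DNA methylation without replicate 2 (95.9) and p53 targets without replicates 3 and 6 (95.6).

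Markers of the mother's reproductive tract were present in some embryos. The oviduct and uterine epithelium list scored 2.0, 5.51, -1.13, -0.27, -1.77, 1.15 and 4.99 in replicates 1 to 7 (SD 2.87, percentile 95.7). Lcn2, a secreted lipocalin of the uterus, had 331, 13743, 0, 0, 5, 208 and 387 counts, and Ovgp1, the oviduct glycoprotein, had 717, 1841, 0, 0, 0, 0 and 67. Blood and immune markers (SD 1.54, percentile 50.0) and stroma and muscle markers (SD 1.24, percentile 1.07) did not spread more than random lists. The macrophage receptor Csf1r had 18 counts in replicate 6 and 0 elsewhere, and the matrix protein Dcn had 592 counts there and at most 11 elsewhere. No cumulus and granulosa marker of 14 and 1 of 10 sperm markers had a mean CPM of 1 or more, so neither list was scored. The list of mitochondrially encoded proteins had 0 of its 13 members in the table. Xist, the RNA of X inactivation, had 37, 65, 0, 12082, 1, 0 and 224 counts, and 0 of 20 Y-linked genes in the table had any count. A count of 0 allows up to 0.0906, 0.175 and 0.182 CPM in replicates 4, 7 and 2, and up to 21.5 CPM in replicate 6. These limits cover counting error only, so a count of 0 does not show absence of a transcript in any embryo.

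**Figure D3:**
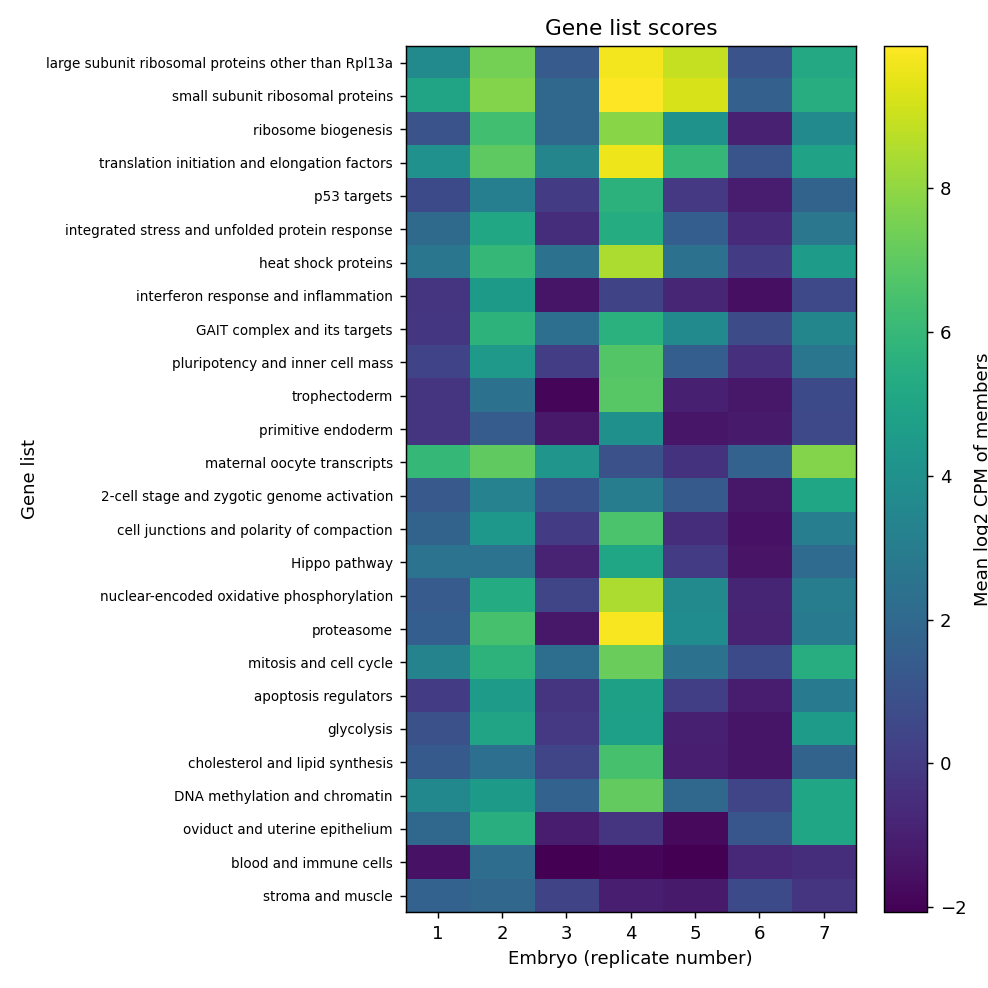
Score of each gene list (rows, mean log2 CPM of its members, colour) in each embryo (columns, replicate number) for the 26 lists scored. Replicate 4 had the highest trophectoderm score, 6.84, beside an oocyte score of 0.92, and replicate 7 had the highest oocyte score, 7.75.

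Scores of 11 of the 26 gene lists followed the Rpl13a level over the 7 embryos, and random lists followed it nearly as closely. All 26 lists had a positive r, and 11 had an adjusted exact permutation p under 0.05 (16 unadjusted, and 4 by Spearman's rho after adjustment). Highest were the Hippo pathway (r 0.957, exact p 0.00179, adjusted 0.0186; rho 0.893, exact p 0.0123, adjusted 0.0533) and cell junctions (r 0.941, exact p 0.00298, adjusted 0.0186; rho 0.929, exact p 0.00675, adjusted 0.0438). The other 9 were primitive endoderm (r 0.929), cholesterol synthesis (0.920), p53 targets (0.907), trophectoderm (0.903), DNA methylation and chromatin (0.896), the integrated stress response (0.895), heat shock proteins (0.869), mitosis (0.868) and pluripotency (0.821), with adjusted exact permutation p from 0.0186 to 0.0455 and rho from 0.714 to 0.929. The 15 lists that did not pass had r from 0.137 for stroma to 0.817 for the proteasome (adjusted exact permutation p 0.764 and 0.0610). Large subunit ribosomal protein genes did not pass (r 0.565, exact p 0.177, adjusted 0.230; rho 0.429, exact p 0.354, adjusted 0.418), nor did small subunit genes (r 0.589, exact p 0.162, adjusted 0.222; rho 0.429, exact p 0.354, adjusted 0.418) or oocyte transcripts (r 0.224, exact p 0.615, adjusted 0.639; rho 0.357, exact p 0.444, adjusted 0.462). Random lists matched on size and expression had median r from 0.696 to 0.858. At most 5% of them reached the observed r only for cell junctions (0.72%) and the Hippo pathway (1.32%). Nearly all of them reached it for oocyte transcripts (100%), oviduct and uterine epithelium (99.95%), 2-cell genes (99.94%), stroma (99.93%) and large subunit genes (99.41%). The same held for ribosome biogenesis (97.94%), interferon response (97.38%) and blood (96.06%). These lists thus followed Rpl13a less closely than most random lists did. The scores of 5 lists had a gap above 0.5 of their own range: interferon response (0.646), blood (0.636), glycolysis (0.571), cholesterol synthesis (0.530) and trophectoderm (0.501). With the gap rule applied to the list scores too, 9 lists passed, without cholesterol synthesis and trophectoderm, an alternative added after seeing the data.

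The number of lists past the threshold changed with the embryos and the scaling used. Without replicates 2 and 4, the farthest from the median Rpl13a level, r of the 11 lists ran from 0.222 to 0.915 and 0 lists passed; the smallest exact p that 5 embryos allow is 0.00833. Leaving out replicate 2, 3, 4 or 6 left 0 lists past the threshold, against 17 without replicate 1 and 15 without replicate 5. Without replicate 2, 3, 4 or 6 the 11 lists had r from 0.623 to 0.964 and adjusted exact permutation p from 0.0506 to 0.255, where 6 embryos allow an exact p of 0.00139 at the smallest. With 1 of replicates 1 to 6 left out, r ran from 0.913 to 0.973 for the Hippo pathway and from 0.886 to 0.979 for cell junctions. In the authors' log2 values r fell to 0.226 for the Hippo pathway and 0.375 for cell junctions (adjusted exact permutation p 0.728 and 0.689), and with medians over members cell junctions did not pass (r 0.883, adjusted exact permutation p 0.0825). Scaling by DESeq2 size factors gave 7 lists, scaling by the library total gave 6, and none passed in the authors' log2 values. Without replicate 7 the Rpl13a values fell into separate clusters (gap 0.554 of the range) and no r was computed. Once replicate 5 was left out, the ribosomal protein lists had r 0.937 for the large subunit and 0.967 for the small subunit (adjusted exact permutation p 0.0331 for each). An r of this height was not particular to them, but the rise in r was larger for them than for any other list. With the scaling of all 7 libraries kept, r without replicate 5 was 0.968 for the Hippo pathway and 0.936 for the proteasome and for the stress response. Other lists were lower, down to -0.128 for stroma. With all 7 embryos, r was already 0.957 for the Hippo pathway, 0.817 for the proteasome and 0.895 for the stress response. It was 0.565 for the large and 0.589 for the small subunit. No random lists were scored without replicate 5. In the 8 relations to technical measures, Rpl13a correlated with the number of genes detected (r 0.879, exact p 0.0147, adjusted 0.0257; rho 0.929, exact p 0.00675; r 0.623 without replicates 2 and 4, the farthest from the median number of genes). With log10 total count the relation did not pass (r 0.722, exact p 0.0677, adjusted 0.0902; rho 0.643, exact p 0.139; r 0.458 without replicates 4 and 6, the farthest from the median total).

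No single gene passed the test of a slope on the Rpl13a level. The edgeR quasi-likelihood test called 0 of 11809 genes (lowest adjusted p 0.114), with 2364 at an unadjusted p under 0.05, 2165 of them higher and 199 lower with Rpl13a. Of 100 random orders of the Rpl13a values, 18 gave at least as many unadjusted calls, and the median was 1733. Past the adjusted threshold, edgeR called up to 1253 genes in a random order. The DESeq2 Wald test called 957 genes, 691 higher and 266 lower with Rpl13a. With 20 random orders of the Rpl13a values, DESeq2 called a median of 833.5 genes, at most 2531, and at least 957 in 8 of the 20. Without replicate 5, edgeR called 3 genes, Adamts3, Pcnxl2 and Spink8, all lower with Rpl13a; they were counted in replicate 6 alone, with 440, 306 and 370 counts.

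Ribosomal protein genes of the large and small subunits moved together over the 7 embryos, and genes of energy metabolism and ribosome biogenesis were correlated with the large subunit list. Of 12 pairs of lists computed, 10 could be tested and 3 passed. The large and small subunit lists had r 0.996 (exact p 0.000198, the smallest possible, adjusted 0.00198; rho 1, exact p 0.000397, adjusted 0.00397; r 0.991 without replicates 4 and 6, the farthest from the median large subunit score). The large subunit list had r 0.916 with nuclear-encoded oxidative phosphorylation (exact p 0.00337, adjusted 0.0169; rho 0.964, exact p 0.00278, adjusted 0.0139; r 0.873 without replicates 4 and 6). With ribosome biogenesis, r was 0.883 (exact p 0.0101, adjusted 0.0337; rho 0.929, exact p 0.00675, adjusted 0.0225; r 0.739 without replicates 4 and 6). With random lists in place of the second list, the median r was 0.433, 0.600 and 0.600 for these 3 pairs, and 0, 0 and 0.06% of 10000 random lists reached the observed r. Relations of the large subunit list to p53 targets (r 0.713, exact p 0.0688, adjusted 0.138; rho 0.643), the stress response (r 0.807, exact p 0.0310, adjusted 0.0774; rho 0.786) and oocyte transcripts (r -0.261, exact p 0.552, adjusted 0.690; rho -0.286) did not pass. Oocyte transcripts were not related detectably to trophectoderm (r -0.0715), pluripotency (r -0.0193), cell junctions (r 0.271) or 2-cell genes (r 0.536), with exact p from 0.219 to 0.967 and rho from 0.107 to 0.464. Random lists in place of the second list had a positive median r with oocyte transcripts (0.294, 0.403, 0.403 and 0.381 in that order), and 99.7, 99.8, 85.2 and 13.6% of them reached the observed r. For the large subunit list with p53 targets, the stress response and oocyte transcripts, the median random r was 0.624, 0.597 and 0.578, and 23.5, 4.03 and 100% reached the observed r. The trophectoderm scores had a gap of 0.501 of their range. By the rule fixed on the first list of a pair, no r was computed for trophectoderm with pluripotency or cell junctions, and its r with oocyte transcripts rests on scores with that gap. The gap was at most 0.5 with the library total, a prior count of 0.5, or without replicate 1, 4, 5 or 6. There r was 0.905 to 0.965 with pluripotency and 0.918 to 0.9497 with cell junctions, with adjusted exact permutation p under 0.05 except for pluripotency without replicate 4 (0.0542). The pair of large and small subunit lists passed with any 1 embryo left out. Those with oxidative phosphorylation and ribosome biogenesis did not pass without replicate 1 (adjusted exact permutation p 0.05 for each), 4 (0.0542 and 0.1), 6 (0.0625 and 0.117) or 7 (0.0694 and 0.0972), and ribosome biogenesis did not after thinning (0.0516). Without replicate 1, 4, 6 or 7, r was still 0.880 to 0.916 with oxidative phosphorylation and 0.812 to 0.897 with ribosome biogenesis. In all, 7 pairs passed without replicate 5 and 1 without replicate 7. Without the 2 embryos farthest from the median of the first list (replicates 4 and 6 for the large subunit, 5 and 7 for oocyte transcripts), or without replicates 3 and 6, 0 pairs passed.

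The main axis of the 7 libraries followed the number of genes detected. Principal component 1 held 37.9% of the variance and component 2 held 18.4%. Component 1 correlated with genes detected (r 0.993, exact p 0.000397, adjusted 0.00159; rho 0.964, exact p 0.00278; r 0.991 without replicates 2 and 4) and with log10 total count (r 0.951, exact p 0.00198, adjusted 0.00529; rho 0.929, exact p 0.00675; r 0.930 without replicates 4 and 6). After thinning to the lowest total, genes detected had the same relation to component 1 (r 0.987, exact p 0.000397, adjusted 0.00159; rho 0.964, exact p 0.00278; r 0.973 without replicates 2 and 4). The share of counts in the 10 most abundant genes was not related detectably to component 1 (r -0.257, exact p 0.579; rho -0.107, exact p 0.840) or to Rpl13a (r -0.286, exact p 0.530; rho -0.357, exact p 0.444).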

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

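All tests of explanations in this part were chosen after the results were seen. Examined were 72 library measures, list scores and gene levels. In 9, all list scores or gene levels, the gap of 1 embryo to the nearest other exceeded Dixon's 95% critical value for 7 embryos. The gap was taken as a share of the range. Chance alone gives about 3.6 of the 72 where the choice of item does not depend on 1 embryo. Of the 9, 5 are genes named for the highest mean CPM of their list, which 1 embryo can carry. Of these, Csf1r and Dcn were flagged as highest, and Omt2b, Eif5a and Yap1 as lowest. Siah2 and Dppa3 were named for a high median CPM. All of these genes were thus chosen by their level, so that figure does not apply to them. Replicate 2 had the highest interferon and inflammation score, 4.51 against 0.58 for the next embryo (gap 0.646 of the range), where Ifitm3, an interferon-induced membrane protein, had 6621 counts. Its blood and immune score, 2.25 against -0.50 (gap 0.636), was also highest, with S100a9 (884 counts) and Tyrobp (457 counts), both of myeloid cells, counted in no other embryo. Replicate 4 was lowest in the oocyte transcript Omt2b, at 1.26 log2 CPM against 9.44 (gap 0.712), and in the ubiquitin ligase Siah2, at 4.12 against 9.78 (gap 0.651). Replicate 5 was lowest in the maternal factor Dppa3, at 6.67 against 10.31 (gap 0.632), and in the Hippo effector Yap1, at -2.07 against 6.55 (gap 0.728). Replicate 3 was lowest in the translation factor Eif5a, at 4.29 against 10.25 (gap 0.688). Replicate 6 was the highest in the macrophage receptor Csf1r, at 6.27 with all others at 0 counts (gap 1), and in the matrix protein Dcn, at 11.31 against 3.26 (gap 0.601). Both are genes named for the highest mean CPM of their list.

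Replicate 4 had counts of more lineage genes than any other embryo; in summed CPM it was highest for trophectoderm (1015, 1014, 4.13, 7675, 519, 3581 and 813 in replicates 1 to 7) but not for pluripotency (6153, 4803, 2942, 5834, 4115, 5809 and 5217). With all libraries thinned to the lowest total, 44 of 54 trophectoderm and pluripotency members had at least 3 counts in replicate 4, against 8, 27, 4, 9, 6 and 16 in replicates 1, 2, 3, 5, 6 and 7, while 6 of 40 oocyte members did, against 29, 32, 21, 5, 13 and 35 (medians of 100 thinnings). Read depth was argued against, since in every thinning replicate 4 had at least 13 more lineage members than any other embryo. Replicates 1, 2, 3, 6 and 7 held at least 4 more oocyte members than replicate 4 in every thinning. This argued against loss from all genes alike out of the transcripts of replicate 4, but did not test loss out of another mixture. Lineage members were also compared with random lists matched on CPM in replicate 4. As few members were found in 0.12 to 0.82, 0.04 to 0.42 and 0 to 0.25% of lists in replicates 1, 3 and 7. In replicates 2 (0.26 to 21.42%) and 6 (34.26%) the comparison did not set lineage members apart. For replicate 5, 25 lineage members were paired with ribosomal protein genes of like CPM in replicate 4. Of these members 5 had at least 3 counts, against 23 of the paired genes (medians). The 95% limits of the shares lay at least 24.6 points apart in every thinning. Ribosomal protein genes were already known to be abundant in replicate 5. The pairs therefore show only that these genes and the lineage members were not lost alike. The earlier comparison of all 54 lineage members with random lists matched on CPM in replicate 4 did not decide (0.17 to 7.04% of lists had as few). Loss of transcripts in general thus stays open for replicate 5. A difference in developmental progress between embryos is a candidate explanation that stays open as a hypothesis; no biological explanation was tested, because the design has 1 group and the labels give every embryo the same stage.

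Replicate 5 had 9 Rpl13a counts in a library rich in other ribosomal protein transcripts. Tests of counting noise were dropped, since they took reads as separate molecules and amplified copies cannot be told from molecules. Relative to its mean in the other embryos, Rpl13a was 3.30 lower on the log2 scale in replicate 5, where the other ribosomal protein genes had a median of 4.30 above theirs and 0 of the 78 others were as low. Random loss of single transcripts during capture may account for this and cannot be told apart: 3 of the 78 others, 3.85% (95% Clopper-Pearson interval 0.800 to 10.8), had a gap as large (-7.61 log2) below the median of the rest in some embryo, all 3 in replicate 1, a test that replaced 2 earlier criteria (in the first the embryo was picked after seeing its values, and in the second the numbers of genes and embryos fixed the outcome). The genotype of the embryo is open and was not tested, since the labels give none, and no biological explanation was tested.

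Of the 11 measured markers of the oviduct and uterus, 6, 9, 1, 3, 1, 3 and 11 had a count in replicates 1 to 7, in different mixtures. Ltf (lactoferrin) had 196, 7645, 162 and 1984 counts in replicates 1, 2, 6 and 7, C3 (complement) 3, 8982, 0 and 566, and Wfdc2 75, 3439, 236 and 866. Reads carried over from replicate 2 were argued against as the only source of the markers. Their ratio to replicate 2 differed between markers by at least 33.9-fold (the smallest lower 95% limit over replicates 1, 6 and 7). The limit compares the highest and lowest ratio of 9 markers, without adjustment for that choice. RNA or cDNA carried over before amplification was not tested. RNA or cells of the tract in the sample, taken up when embryos were flushed, is a hypothesis that cannot be told apart from expression by the embryos. Either could make the markers vary together, so the spread of the list score cannot decide between them. That spread was itself unsettled. The SD of the list score stood at percentile 95.7 of random lists, but at 83.5 with medians over members. With 1 embryo left out it ran from 68.7 (without replicate 2) to 98.6 (a test that replaced a count of markers). Replicate 4 held Muc1 (1217 counts), Tppp3 (472) and Wfdc2 (296), and whether the embryos themselves express some of the 11 was not tested.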

How the results depend on the processing

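Alternatives chosen after seeing the data were those without replicates 3 and 6, the residuals on log10 total count, the comparison with random lists, the gap rule on both measures, each gene's own prior, the bias-adjusted edgeR fit and the one without Rn45s, Rnr1, Rnr2 and Lars2. The number of lists related to Rpl13a, 11, was 7 with DESeq2 size factors, 6 with the library total, 0 with the authors' table, 3 with medians over members, 0 without the 2 farthest embryos, 0 without replicates 3 and 6, 3 for residuals and 2 when r also had to exceed that of 95% of random lists. With the gap rule on both measures it was 9. Leaving out 1 embryo gave 0 (without replicates 2, 3, 4 or 6) to 17 (without 1). The number of related list pairs, 3, was 5 with the library total or a prior count of 0.5, 0 without the 2 farthest embryos and 0 without replicates 3 and 6; leaving out 1 embryo gave 1 (without replicate 7) to 7 (without 5), and the pairs with oxidative phosphorylation and ribosome biogenesis lost their call without replicate 1, 4, 6 or 7. It was also 3 with the gap rule on both measures, and 3 when r had to exceed that of 95% of random lists. With 5 embryos the smallest exact p is 0.00833, so part of these losses comes from fewer samples; the cause of the others was not tested. The DESeq2 size factors moved single libraries by -0.68 to 0.98 log2 against TMM.

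Genes more variable than the trend by edgeR numbered 0 (68 at an unadjusted p under 0.05), also under every alternative run except the authors' table, with 2; the cause was not tested. The slope on Rpl13a called 0 genes except by the DESeq2 Wald test, with 957, and without replicate 5, with 3 (range 0 to 3 over embryos left out); without replicate 7 the values fell into clusters, and a fit made regardless called 1721 genes (1614 higher, 107 lower). Lists of high spread, 13, numbered 7 with medians over members and 10 to 14 with 1 embryo left out. Ribosomal protein genes with a larger SD than Rpl13a, 62, numbered 39 without replicates 3 and 6 and 51 to 66 with 1 embryo left out. The r of oocyte transcripts with Rpl13a, 0.224, was -0.685 in the authors' table, -0.0473 after thinning, and -0.0327 (without replicate 5) to 0.777 with 1 embryo left out; for large subunit genes r was -0.0469 for residuals. Neither relation passed the threshold with all 7 embryos; the cause of the changed sign was not tested. Leaving out mitochondrially encoded genes was not run, since the table held 0 of the 13 proteins; Rnr1 and Rnr2 match no annotated gene name, and whether they are mitochondrial was not determined. Depth limits replicate 6 most, where 1 count equals 7.16 CPM. No paired analysis was possible because the labels give 1 group, with no replicate numbers shared across groups.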

Other observations

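No test of an explanation is reported in this part, and the genes below were chosen after their values were seen. Zfp352, a 2-cell zinc finger gene, was at 351, 67.8, 375, 15.4, 0, 0 and 453 CPM in replicates 1 to 7, Tcstv3 at 278 CPM in replicate 7, 143 CPM in replicate 2 and 45.5 CPM in replicate 1, and Tmem92 at 464 CPM in replicate 7 and 158 CPM in replicate 6 (22 counts). Among stress genes, Hspa5, the chaperone of the endoplasmic reticulum, had 33993 counts (1026 CPM) in replicate 4, 1629 (589 CPM) in replicate 5 and 0 in replicate 6. Cdkn1a (p21), a p53 target, was at 141 CPM in replicate 4 and 112 CPM in replicate 2, with 0 counts in replicates 5 and 6. In the GAIT list, Vegfa had 2 counts in replicate 1, 1 in replicate 7 and 0 elsewhere, and Gapdh was at 60.5 CPM in replicate 4 and 43.0 CPM in replicate 6 (6 counts), with 0 counts in replicates 1, 3 and 5. Proteasome and chaperone genes were abundant in replicate 4, with 44405 counts of Psma7 (1341 CPM) and 52203 of Hspa8 (1576 CPM).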
